A study of Homo sapiens with 6 samples.

How the data were processed

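RNA from human islets was sequenced after 24 h in 25 mM glucose with or without 1 µM SRI-37330, from libraries made with a stranded mRNA kit, per the labels. The values are a signal deposited by the authors: gene-level estimated counts divided by a normalization factor, named DESeq normalized counts. The submitters' processing notes name STAR, Salmon and DESeq2 and the genome build hg38. Versions, settings, the annotation and any filter are not given in the sources used here. The table held 58037 genes and 6 value columns, all matched to the labels. Low values are mostly but not nearly all whole multiples of 1 step per library (75.6% to 79.1% within 0.1 step, where 95% was required to recover reads), so no count-based test was run and depths are approximate. The normalized counts of a library summed to between 36000000 and 39800000.

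Gene positions and types came from GENCODE release 29, matched by identifier for 57388 genes. Some 27 symbols had turned into dates. Those genes were kept by identifier and are not named here, and 517 Y-linked, XIST and TSIX entries were left out of all tests. Genes with a mean normalized count of at least 10 were tested (20190 genes) on log2(normalized count + 1), so fold changes are on that scale and understate the change of low genes. Tests used R 4.3.3, limma 3.58.1 and the package data.table (version 1.17.8), and figures Python 3.11.15 with matplotlib 3.10.9. The main test was limma with a variance trend on group alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For TXNIP an exact permutation test was added, which with 3 against 3 values cannot go below p = 0.1. Because depths are approximate, no counting intervals are given, and errors are those between replicates.

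The labels number the libraries 1 to 3 in both groups without saying what the number stands for. Whether numbers pair the libraries was checked from the correlation of the libraries' deviations from their group means over genes. Same-numbered libraries gave 0.526, 0.794 and 0.680, all above the 0.1 required, and different-numbered libraries gave −0.64 to 0.16. The pairing therefore comes from the data and the shared numbers, and the fit with the replicate number as a block is given beside the main one. Nothing states that the replicates are separate donors or cultures. Unpaired p-values measure only the spread between the libraries of a group, and paired ones only the spread of the differences within a number. The correlations within a number argue against a spread between numbers that arose in single libraries alone. What the numbers stand for stays unknown, and the spread of the differences within a number may be technical.

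Before the data were examined, the 36 gene lists (730 genes, all found in the table), the tests, the alternatives and the rule for named genes were fixed. The rule names TXNIP, the other arrestin family genes and 5 islet hormone genes. It also names up to 12 genes per direction past the threshold with a mean of at least 50 and non-overlapping groups, or the 5 with the smallest p where fewer than 5 pass, and up to 4 members per list. Pseudogenes are passed over, and some genes that the rule names are not reported here. After the data were examined the same rule was applied to the paired fit, with the same direction in all 3 pairs in place of non-overlap, and further genes were named: TGFB2, TGFB3, EDN1, JAG1, TTR, GC, CTRB1, UCN3, MT-CO1, SLC6A6, C2CD4A, C2CD4B, DGCR9, AC000095.2, HMGN2P3 and FP671120.3. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation, camera has only the residual degrees of freedom of the fit, 4 unpaired and 2 paired, and so little power. Failing it does not show that correlation between members made a call. The extracellular matrix list failed it in the paired fit although its estimated correlation, −0.018, was below the preset.

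The fits were tested on data simulated for the 20190 genes, with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold. Means were taken per replicate number and the residual spread from the paired fit. Counting noise was added on top, although that spread already holds some. The pairing was thus built in, so the recovery of the unpaired fit holds only for libraries paired in this way. The unpaired limma fit recovered 0, 0 and 0 of them. The paired fit recovered 26.9%, 71.6% and 92.4%, with 21 false calls among 148 (14.2%). The alternatives covered the pseudocount, the filter, rescaling, the variance model, library weights, the fold threshold, the block and each replicate left out.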

Results

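Gene expression was measured by RNA sequencing in human pancreatic islets, the clusters of hormone-secreting cells of the pancreas. The islets were kept for 24 h in 25 mM glucose without (control) or with 1 µM SRI-37330, a small molecule that the series title describes as regulating TXNIP expression and the action of glucagon. There were 3 control and 3 treated libraries, numbered 1 to 3 in each group. The most frequent low value of each library, taken as its step, gave approximate depths of 26900000, 40200000 and 32900000 reads for control replicates 1 to 3. For treated replicates 1 to 3 the depths were 39900000, 38300000 and 35400000 reads, so pair 1 was the least balanced. The single comparison of the design, treated against control, asks which transcripts differ in high glucose when the compound is present.

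Libraries with the same replicate number resembled each other more than libraries of the same treatment did. The first principal component held 60.6% of the variance and set replicate number 2 of both groups apart, the second held 16.2% and separated numbers 1 and 3, and the third held 9.90% and separated treated from control libraries. Acinar markers, mostly digestive enzymes of the exocrine pancreas, made up 4.64% of the normalized counts in control replicate 2 and 3.73% in treated replicate 2, against 0.175% to 0.411% in the other 4 libraries. Values are given from a fit without pairing, taken as the main one, and from a fit with the replicate number as a block, called paired here.

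**Figure D1:**
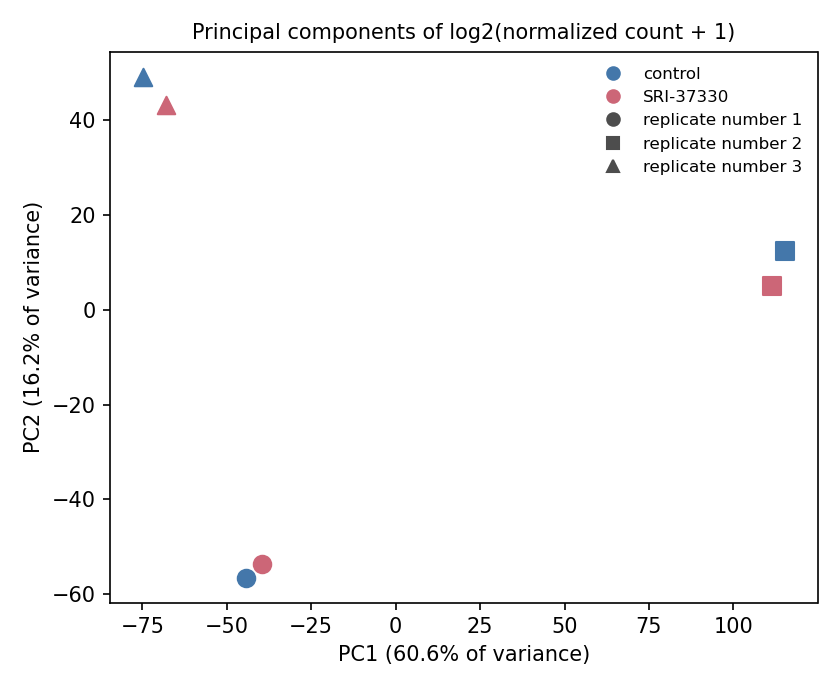
Scores of the 6 libraries on the first (x axis, 60.6% of the variance) and second (y axis, 16.2%) principal components of log2(normalized count + 1), in arbitrary units. Color gives the treatment and symbol the replicate number, and libraries of the same number lie next to each other.

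TXNIP (ENSG00000265972), which encodes thioredoxin-interacting protein, an arrestin family member that binds thioredoxin, had 15750 ± 2130 normalized counts in control and 8190 ± 742 in treated islets (mean ± SD, n = 3 per group). This was a log2 fold change of −0.94, or 1.92-fold lower, and the groups did not overlap. TXNIP was lower in 3 of 3 pairs, with log2 changes of −1.09, −0.87 and −0.85. The gene lies on the minus strand of chromosome 1 at 145992435 to 145996600 (GRCh38). In the unpaired limma fit TXNIP was not past the threshold after Benjamini-Hochberg adjustment over 20190 genes (SE 0.19, adjusted p = 1.00), and in the paired fit it fell (SE 0.094, 95% interval −1.16 to −0.72, adjusted p = 0.0244). Before adjustment the unpaired limma p of TXNIP, a gene named in advance, was 0.00235. The exact two-sided permutation test of 3 against 3 values gave p = 0.1, the smallest it can give. The paired call was lost without replicate 1 (log2 fold change −0.86, adjusted p = 0.0569), without replicate 3 (−0.98, adjusted p = 0.0911) and in limma without the variance trend (adjusted p = 0.403), over a range of adjusted p from 0.0124 to 0.403 in the paired alternatives. With the replicate number as a random effect, TXNIP was not past the threshold (adjusted p = 0.0542).

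No other arrestin family gene passed the threshold in either fit. ARRDC4 had a log2 fold change of −0.32 (paired SE 0.094, adjusted p = 0.225) and was lower in 3 of 3 pairs. ARRDC2 had −0.24, ARRDC3 0.28, ARRDC1 0.18, ARRB1 0.23 and ARRB2 0.0047, and ARRB2 turned to the lower side under upper-quartile and quantile rescaling. The family list had a median of 0.0047, which also turned negative under those rescalings, while its mean was −0.12 and camera, a test of a list against all other genes, placed it on the lower side without passing (paired adjusted p = 0.336). Adjusted over the list alone, 2 of its 7 tested members were lower in the paired fit and 1, TXNIP, in the unpaired fit.

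MLXIPL, which encodes the glucose-responsive transcription factor ChREBP, fell in the paired fit from 9785 ± 4303 to 5559 ± 2395 normalized counts (log2 fold change −0.82, SE 0.096, adjusted p = 0.0282) and was lower in 3 of 3 pairs. In the list of ChREBP and glucose-responsive genes, which holds TXNIP, ARRDC4 and MLXIPL, 2 of 18 tested members fell, 16 did not pass, and adjusted over the list alone 3 were higher and 3 lower. In the unpaired fit 1, again TXNIP, was lower adjusted over the list alone. Its median was 0.0040, negative under upper-quartile and quantile rescaling, its mean was −0.019 and its camera test did not pass (paired adjusted p = 0.725).

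The unpaired limma fit called 0 of 20190 genes, with a smallest adjusted p of 0.717. It held 256 genes at an unadjusted p under 0.05, against 1009.5 expected by chance, and limma-voom and array weights also called 0. The paired fit held 2843 at an unadjusted p under 0.05, against the same 1009.5. The groups did not overlap for 5.63% of the genes, against 10% by chance, and 37.2% moved the same way in 3 of 3 pairs, against 25% by chance. Both unpaired comparisons with chance take no account of the pairing. The paired fit called 70 genes, 50 higher and 20 lower, all moving the same way in 3 of 3 pairs, and 35 of them changed by at least 2-fold. The 70 calls depend on the pairs and on the model: there were 6 without replicate 1 (3 of them among the 70), 163 without replicate 2 (60 of them among the 70) and 1 without replicate 3 (0 among the 70), 0 in limma without the trend, and 8 with the replicate number as a random effect, TXNIP not among them. In data simulated from these libraries with the pairing built in, 21 of 148 paired calls (14.2%) were false.

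SLC2A2 (ENSG00000163581), which encodes the glucose transporter GLUT2, rose in the paired fit from 546 ± 359 to 2146 ± 1118 normalized counts (log2 fold change 2.09, SE 0.15, adjusted p = 0.0151), and its groups did not overlap. MIR29B2CHG, a host transcript of miR-29 microRNAs, rose by 1.96 (SE 0.14, adjusted p = 0.0151), and the keratins KRT6B and KRT17 rose by 1.95 and 1.31. PAPPA, a protease that cleaves insulin-like growth factor binding proteins, rose by 1.77, CALCB by 1.46 and the matricellular gene CTGF by 1.33. The chemokine CXCL12 rose by 1.33, PCDH7 by 1.28, the nuclear receptor coactivator NCOA3 by 1.24 and the copper transporter ATP7B by 1.13. These genes had paired adjusted p-values from 0.0151 to 0.0478 in limma after Benjamini-Hochberg adjustment, and each was higher in 3 of 3 pairs. Among the other calls, chosen after their values were seen, TGFB3 rose by 1.08, EDN1, the endothelin-1 gene, by 1.05, the Notch ligand JAG1 by 1.01 and TGFB2 by 0.88.

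STUM fell in the paired fit from 208 ± 90.1 to 4.82 ± 1.85 normalized counts (log2 fold change −5.11, SE 0.46, adjusted p = 0.0226), a treated level near the bottom of the measured range. The collagen gene COL24A1 fell by 2.47, AP001793.2 by 2.09, IGFN1 by 2.03 and PTPRC, the leukocyte antigen CD45, by 1.94. The small heat shock gene HSPB6 fell by 1.71, the immediate early transcription factor EGR1 by 1.32, CUZD1 by 1.12 and G0S2, an inhibitor of the lipase ATGL, by 1.01. FP236383.3 and FP236383.2 each fell by 0.83, and together with FP671120.3 they are near-identical copies between which reads cannot be assigned with certainty. These genes had paired adjusted p-values from 0.0226 to 0.0478 in limma after Benjamini-Hochberg adjustment, and each was lower in 3 of 3 pairs. In the unpaired fit, among genes other than pseudogenes with a mean of at least 50, those with the smallest p, none past the threshold, were SULF2, PAPPA, EEF2K, SIPA1L2 and KIRREL3 on the higher side and STUM (adjusted p = 0.717), MCM3AP, TXNIP, RAB3IL1 and AP001793.2 on the lower side.

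Of the islet hormone genes, GCG, the glucagon gene, rose in the paired fit (log2 fold change 0.61, SE 0.088, adjusted p = 0.0478), with pair changes of 0.61, 0.68 and 0.54. The call on the GCG log2 fold change, paired fit, was lost in 9 of 15 alternatives, at adjusted p = 0.0757, 0.0540 and 0.190 without replicates 1, 2 and 3 and up to 0.403 in limma without the trend. Its unpaired log2 fold change ranged from 0.0090 without control replicate 2 to 1.18 without treated replicate 2. Those fits kept the partner of the left-out library, so the replicate numbers were unbalanced. In the paired alternatives the change stayed between 0.57 and 0.65. GCG was the most abundant transcript of treated replicate 1, with 6.89% of the normalized counts, and MT-CO1 was that of the other 5 libraries. The insulin gene INS had a log2 fold change of 0.28 (SE 0.12, adjusted p = 0.380) and was higher in 2 of 3 pairs. The amylin gene IAPP had 0.78 (adjusted p = 0.135), with pair changes of 0.43, 1.39 and 0.51, a paired value of 0.47 without replicate 2 and an unpaired value of 0.029 without control replicate 2. PPY, the pancreatic polypeptide gene, had 0.48 (adjusted p = 0.103) and the somatostatin gene SST −0.21 (adjusted p = 0.414), and none of these 4 was past the threshold. All 5 had an adjusted p of 1.00 in the unpaired limma fit.

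**Figure D2:**
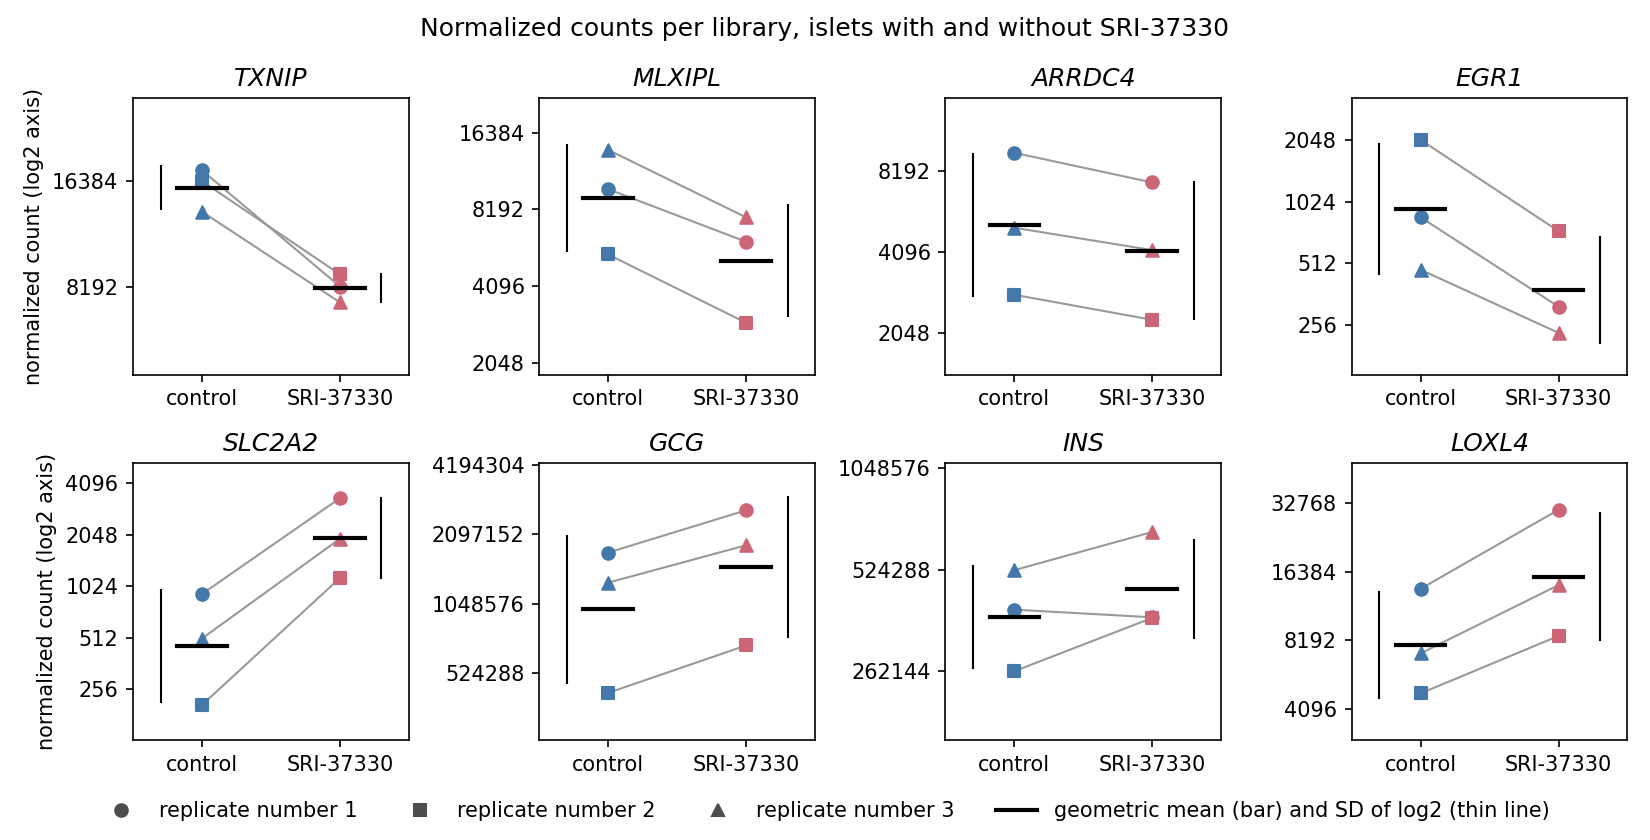
Normalized counts (y axis, log2 scale) of 8 genes in the 3 control (blue) and 3 SRI-37330 (red) libraries (x axis), with gray lines joining the same replicate number, a thick bar at the geometric mean and a thin line for the SD of log2 values. TXNIP was lower in 3 of 3 pairs without overlap of the groups, SLC2A2 and GCG were higher in 3 of 3 pairs, and INS was higher in 2 of 3.

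Beta cell markers were on the higher side as a group. All 22 had a positive log2 fold change (median 0.33), except that UCN3 turned to the lower side under upper-quartile and quantile rescaling. In the paired fit SLC2A2, ENTPD3 (0.91) and NPTX2 (0.71) rose and 19 members did not pass, among them the transcription factor genes PDX1 (0.55) and MAFA (0.50), and adjusted over the list alone 12 were higher. The camera test passed in the unpaired (adjusted p = 0.00194) and paired fits (adjusted p = 1.35e-13), but with adjusted p = 0.938 and adjusted p = 0.374 with an estimated correlation it did not. Acinar shares were lower in each treated library than in its partner, 0.224% against 0.411%, 3.73% against 4.64% and 0.175% against 0.267%. The unpaired call of the beta list was lost without treated replicate 3 (median 0.058) and without control replicate 2 (median −0.071, camera adjusted p = 0.718). Leaving out 1 library in this way unbalances the replicate numbers. In the paired alternatives the median of the beta list stayed between 0.30 and 0.46.

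Alpha cell markers had 16 of 18 members positive (15 under upper-quartile and quantile rescaling, median 0.26). GCG and LOXL4 (1.00) rose in the paired fit, 16 did not pass, and adjusted over the list alone 5 were higher (camera paired adjusted p = 0.000117, adjusted p = 0.374 with an estimated correlation). TTR and GC, also on that list, had −0.17 and −0.25. Delta, PP and epsilon cell markers had a median of 0.23 with 0 of 13 past the threshold and 4 higher adjusted over the list alone (camera paired adjusted p = 0.0184, adjusted p = 0.545 with an estimated correlation). That call was lost without replicate 2 (adjusted p = 0.267) and with limma-voom weights (adjusted p = 0.0743).

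Acinar cell markers were on the lower side in the paired fit, with 22 of 24 members negative (median −0.64). CTRB2, a chymotrypsinogen gene, fell by 0.63, 23 did not pass, and adjusted over the list alone 20 were lower and 1 higher (camera paired adjusted p = 9.18e-15, adjusted p = 0.425 with an estimated correlation). CTRB1, a paralog that can share reads with CTRB2, had 0.063. Duct cell markers had 15 of 17 members positive (median 0.26), 0 past the threshold and 4 higher adjusted over the list alone (camera paired adjusted p = 4.88e-05, adjusted p = 0.374 with an estimated correlation). Stellate and fibroblast markers had 14 of 16 positive (median 0.47), with COL3A1 (0.59) and SFRP2 (1.06) rising, 14 not passing and 9 higher adjusted over the list alone (camera unpaired adjusted p = 0.000211 and paired adjusted p = 1.39e-07, adjusted p = 0.374 for the paired test with an estimated correlation). Extracellular matrix and TGF-beta targets had 16 of 18 positive (median 0.49), with CTGF and COL4A1 (0.68) rising, 16 not passing and 11 higher adjusted over the list alone (camera unpaired adjusted p = 0.000211 and paired adjusted p = 2.75e-10, adjusted p = 0.374 for the paired test with an estimated correlation). Without control replicate 3 the unpaired calls of the stellate list (median 0.28, adjusted p = 0.117) and of the matrix list (median 0.073, adjusted p = 0.258) were lost. Without treated replicate 2 they were also lost, the stellate list at a median of 0.13 (adjusted p = 0.173) and the matrix list at 0.12 (adjusted p = 0.282). Endothelial markers (median −0.012, 0 of 12 past the threshold) and immune cell markers (median 0.12, with PTPRC alone of 15 past it) were not called.

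Mitochondrially encoded mRNAs, which encode respiratory chain and ATP synthase subunits, were on the lower side in both fits. All 13 were lower in 3 of 3 pairs (median −0.31), although 1 turned positive and the median was −0.15 under quantile normalization. None passed over all genes in the paired limma fit and 11 were lower adjusted over the list alone, and their share of the normalized counts averaged 20.4% in control and 16.8% in treated libraries. The camera test gave an unpaired adjusted p = 0.000265 and a paired adjusted p = 6.21e-11, and adjusted p = 0.425 for the paired test with an estimated correlation. The unpaired call was lost under quantile normalization (adjusted p = 0.0720), without control replicate 3 (median −0.16, adjusted p = 0.117) and without treated replicate 2 (median −0.19, adjusted p = 0.0708). Metallothioneins, which bind zinc and copper, had 6 of 7 members negative (median −0.61), 0 past the threshold and 4 lower adjusted over the list alone (camera unpaired adjusted p = 0.00720 and paired adjusted p = 0.000784, adjusted p = 0.374 for the paired test with an estimated correlation). The paired call of the metallothioneins was lost without replicate 1 (median −0.33, adjusted p = 0.0801). Their unpaired call was lost without control replicate 2 (median −0.32, adjusted p = 0.369) and without treated replicate 1 (median −0.22, adjusted p = 0.710). MT2A had −0.85 and MT1G −0.80.

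Lipid synthesis lists were on the higher side in both fits. Cholesterol synthesis genes had 19 of 24 members positive (18 under upper-quartile and quantile rescaling, median 0.20), 0 past the threshold and 4 higher adjusted over the list alone (camera unpaired adjusted p = 0.00123 and paired adjusted p = 0.000134, adjusted p = 0.374 for the paired test with an estimated correlation). Fatty acid synthesis and storage genes had 15 of 18 positive (13 under those rescalings, median 0.34). SCD, the stearoyl-CoA desaturase gene, rose by 0.68, 17 did not pass and 7 were higher adjusted over the list alone (camera unpaired adjusted p = 0.00294 and paired adjusted p = 0.000261, adjusted p = 0.374 for the paired test with an estimated correlation). ATF4 and integrated stress response genes had 16 of 22 positive (median 0.24), 0 past the threshold and 2 higher adjusted over the list alone (camera unpaired adjusted p = 0.0215 and paired adjusted p = 0.00398, adjusted p = 0.466 for the paired test with an estimated correlation). The paired ATF4 call was lost without replicate 3 (adjusted p = 0.0503). The unpaired call of the cholesterol list was lost without control replicate 3 (median 0.11, adjusted p = 0.117) and without treated replicate 2 (median 0.11, adjusted p = 0.0998). That of the fatty acid list was lost without control replicate 2 (median 0.094, adjusted p = 0.0683), and both it and that of the ATF4 list without the filter on low values (adjusted p = 0.0545 each). The unpaired ATF4 call was also lost without control replicates 1 (median 0.13, adjusted p = 0.437) and 3 (median 0.091, adjusted p = 0.129). It was lost as well without treated replicates 2 (median 0.14, adjusted p = 0.331) and 3 (median 0.21, adjusted p = 0.0768).

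The alpha, delta (with PP and epsilon), acinar and duct lists passed in the paired fit alone (unpaired camera adjusted p = 0.147, 0.391, 0.104 and 0.301). A further 5 lists did the same. Glycolysis genes had a median of 0.13, with SLC2A2 and LDHA, a lactate dehydrogenase gene (0.96), rising and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.509 with an estimated correlation). The glycolysis call was lost when members shared with other lists were left out (adjusted p = 0.427). Glucagon, incretin and nutrient receptors had a median of 0.23, with the receptor genes IGF1R (0.65) and GRIA3 (0.78) rising and 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00658, adjusted p = 0.374 with an estimated correlation). Inflammasome and NF-kB targets had a median of 0.35, 0 of 22 past the threshold and 9 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00677, adjusted p = 0.425 with an estimated correlation), and the call was lost without replicate 2 (adjusted p = 0.0947). The cytokine genes CXCL8 and IL1B on that list had 1.01 and 0.99, and the NF-kB inhibitor gene NFKBIA had −0.51. Cytosolic ribosomal proteins had a median of 0.084 with 0 of 50 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.633 with an estimated correlation). That call was lost without replicate 2 (median 0.027, adjusted p = 0.273) and without replicate 3 (median 0.077, adjusted p = 0.0503). Upper-quartile (median 0.057, adjusted p = 0.0547) and quantile rescaling (median 0.044, adjusted p = 0.340) also lost it. Interferon-stimulated genes had 16 of 22 members negative (17 under upper-quartile and quantile rescaling, median −0.20), 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0261, adjusted p = 0.398 with an estimated correlation). The interferon call was lost without replicate 2 (adjusted p = 0.136), without replicate 3 (adjusted p = 0.0593) and among genes with a mean of at least 50 (adjusted p = 0.0517).

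**Figure D3:**
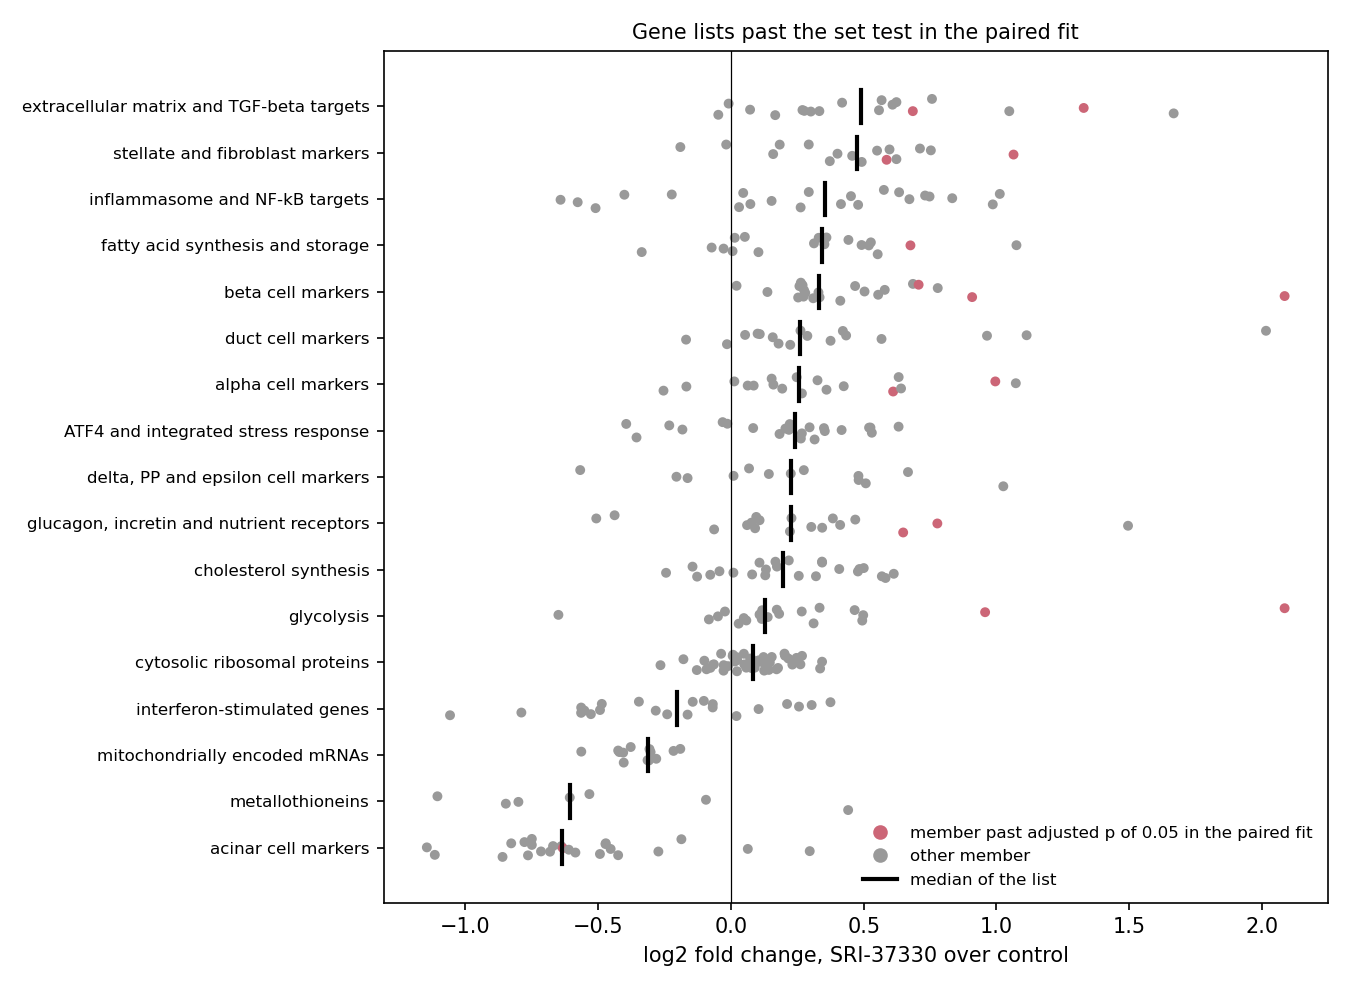
Log2 fold change of SRI-37330 over control (x axis) for each tested member (points) of the 17 gene lists (y axis) past the camera threshold in the paired fit, with the median as a black bar and members past an adjusted p of 0.05 in red. The median is 0.33 for the beta list, −0.31 for the mitochondrially encoded mRNAs (−0.15 under quantile normalization) and −0.64 for the acinar list. No list passes with an estimated correlation, a test that has only 2 residual degrees of freedom here.

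The remaining lists did not pass in either fit. Islet transcription factors had a median of 0.089, and in the paired fit ISL1 (0.77), needed for endocrine cell development, rose while MLXIPL fell. Among hypoxia-inducible genes (median 0.084) LDHA rose, and among immediate early genes (median −0.033) EGR1 fell. None of the members passed in the paired limma fit for thioredoxin and antioxidant genes (median 0.068), hormone secretion machinery (0.095), endoplasmic reticulum chaperones (0.062), apoptosis regulators (0.12), p53 targets (0.13), fatty acid oxidation and PPAR targets (−0.060), nuclear oxidative phosphorylation genes (0.031), cell cycle genes (0.055), xenobiotic response genes (0.17), nuclear-retained and small-RNA-host transcripts (0.13), and G protein signalling and cAMP targets (−0.067), nor for heat shock genes, whose median of 0.011 turned negative under upper-quartile and quantile rescaling. Of the nuclear-retained and small-RNA-host transcripts 11 were positive and 3 negative, and adjusted over the list alone 1 was higher and 2 lower. MALAT1 (−0.71 to −0.43) and NEAT1 (−0.79 to −0.54) were on the lower side in all paired alternatives. Of all 36 lists, camera called 8 unpaired and 17 paired, among them all 8, and 0 with an estimated correlation in either fit or in the directional test of fry. With an estimated correlation, camera had only 4 (unpaired) and 2 (paired) residual degrees of freedom. Its lack of calls therefore does not show that correlation between members accounts for the others. The mixed test of fry, which asks whether members change in either direction, passed for 28 lists paired and 0 unpaired. Of the 8 unpaired calls, 1 was lost without control replicate 1 and 5 without control replicate 3. Without control replicate 2, 2 were lost besides that of the beta list, which also turned. Leaving out treated replicate 1 lost 1 call, treated replicate 2 lost 5 and treated replicate 3 lost 2. Each of these fits kept the partner of the left-out library, which unbalances the replicate numbers.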

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

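All alternatives within the paired fit and the random-effect model were chosen after seeing the data, and the others before. The planned count-based tests were not run, since whole reads could not be recovered. The cause of a difference was not tested unless given here. Adding the replicate block, which makes the fit paired, moved the genes called from 0 to 70 (50 higher, 20 lower) and the lists from 8 to 17, and TXNIP (log2 fold change −0.94) passed, since the median residual SD was 0.49 without and 0.21 with the block. With the replicate number as a random effect 8 genes were called, 4 higher and 4 lower (consensus correlation 0.760). Without the block, limma without the trend called 1 gene, 0 higher and 1 lower (HMGN2P3). All other unpaired alternatives called 0. Lists called were 6 without a filter on low values (the ATF4 and fatty acid lists lost), 7 under quantile normalization (the mitochondrially encoded mRNAs lost), 0 with an estimated correlation, 0 by fry in direction and 0 by its mixed test, and 8 to 15 with 1 library left out.

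In the paired fit, calls (higher, lower) were 37 (25, 12) without a filter, 41 (28, 13) after upper-quartile rescaling, 36 (25, 11) after quantile normalization, 0 (0, 0) without the trend, 109 (74, 35) with robust empirical Bayes and 119 (83, 36) with limma-voom weights. Without the trend TXNIP, at −0.94, was no longer past the threshold. Lists called were 0 with an estimated correlation, 0 by fry in direction and 28 by its mixed test. With 1 replicate number left out, which leaves 1 residual degree of freedom, calls ranged from 1 to 163 (0 to 116 higher, 1 to 47 lower) and TXNIP from −0.98 to −0.86. All 70 genes kept their direction in each paired alternative that tested them. For the left-out replicates this was fixed in advance, since all 70 moved the same way in every pair. Single libraries also moved changes in the unpaired fit, where leaving out 1 library keeps its partner and unbalances the replicate numbers. The following ranges therefore also hold differences between replicate numbers. With 1 library left out of the unpaired fit, log2 fold changes ranged from 0.0090 to 1.18 for GCG, 0.029 to 1.44 for IAPP, −0.48 to −0.010 for ARRDC2, 0.13 to 0.49 for ARRDC3, −0.26 to 1.21 for PPY, −0.084 to 0.61 for ARRB1, −0.75 to 0.13 for ARRDC4, −0.16 to 0.093 for ARRB2, −0.95 to 0.44 for SST, −0.060 to 0.46 for ARRDC1 and −0.0061 to 0.51 for INS, and the beta list median from −0.071 to 0.94. In the paired alternatives GCG ranged from 0.57 to 0.65, IAPP from 0.47 to 0.95 and the beta list median from 0.30 to 0.46. In the paired fit ARRB2 ranged from −0.14 to 0.18 and UCN3 from −0.033 to 0.058. Rescaling turned the ARRB2 log2 fold change to −0.023 (upper quartile) and −0.032 (quantile) in both fits, and the UCN3 log2 fold change, paired fit, to −0.0063 and −0.0011. Depth limits what can be said of genes near the floor, such as STUM in treated libraries.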

Other observations

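The tests on the beta cell markers and on the glucose-responsive genes were chosen only after their results were seen. The test on the acinar markers and the splits of the libraries were set before their own results were seen, but after the patterns that they examine.

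Some calls of the paired fit lie outside the lists. AC000095.2, a pseudogene transcript, rose from 5.14 ± 2.26 to 91.8 ± 17.6 normalized counts (paired limma adjusted p = 0.0235), and the overlapping gene DGCR9 on the same strand differed by 49.1, −53.6 and 1.78 normalized counts in the 3 pairs. HMGN2P3, also a pseudogene, had 34.4 ± 4.71 normalized counts in control libraries and was listed at 0 in all 3 treated libraries. C2CD4A and C2CD4B, neighboring genes, rose by 1.03 and 0.91 on the log2 scale, and the taurine transporter gene SLC6A6 rose by 1.12. These genes were chosen after their values were seen. PTPRC fell by 1.94, while the other 14 immune markers had a median of 0.14 (SD 0.43).

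Other splits of the libraries were too few for a share under 0.05. Without pairing the outcome was also fixed, since no split can give fewer than the 0 genes of the real one (10 of 10 gave at least as many, with a highest other of 1). Of the 4 splits that part all pairs, 1 gave as many genes as the real split, the real one itself, with 70 against a highest other of 0.

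Beta cell markers were higher while acinar markers were lower, and a smaller acinar share would raise all other transcripts alike. The measured fall of the share of the 24 acinar markers raises other transcripts by at most 0.014 (log2) in a pair. The beta medians were 0.33, 0.60 and 0.35 (SD 0.15). In each pair such a rise would need a loss above the whole marker share of the control library. In pair 2 this was 34.0% of the counts, against a marker share of 4.64%. These markers are only a part of the RNA of acinar cells, and normalization can scale away a rise shared by most transcripts. The comparison therefore cannot exclude fewer acinar cells. Medians of 7 other cell types differed between types (p = 0.0204, permuting genes between lists), but not past 0.05 without the endothelial and immune lists (permutation p = 0.298). Permuting treats genes as independent, while estimated correlations within these lists ran from 0.072 (alpha) to 0.327 (beta) in the paired fit. The permutation p may thus be too small, and it does not measure the spread between replicates. If scaling between libraries were the cause, rescaling would end the rise of the beta list, but the lowest median over 3 rescalings was 0.304. More beta cells alone would raise all markers by 1 factor only if no other cells expressed them. The 22 markers differed between genes (permutation p = 0.0001, the smallest possible here, and 0.0133 without SLC2A2). Expression in other cells was not tested, so this difference alone does not decide whether cell numbers were the whole cause. A response of beta cells to the compound may contribute and was not tested, and how far cell numbers account for the rise stays open.

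Acinar markers were lower in the paired fit. Fewer acinar cells as the whole cause would lower all 24 markers by 1 factor only if no other cells expressed them and paralogs shared no reads. The markers differed between genes (permutation p = 0.0009). Neither condition was tested, so this difference does not exclude fewer acinar cells as the whole cause. Cell loss, in part or in whole, and a response of acinar cells both stay open, and the latter was not tested.

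TXNIP and MLXIPL fell in the paired fit and ARRDC4 was lower without passing. All 18 tested members of the list of glucose-responsive genes had a median of 0.0040 (SD 0.39), which turned negative under upper-quartile and quantile rescaling. This lay above the change of MLXIPL by 0.82, more than the SD, which argues against a fall of the set by as much as MLXIPL. It lay above the change of ARRDC4 by 0.32, less than the SD. That SD is the spread among members, not the error of the median, so this comparison cannot decide on a fall of that size. Of the members 10 were positive and 8 negative, or 8 and 10 under those rescalings, and camera did not call the set (paired adjusted p = 0.725). A response of a few of these genes to the compound may be an explanation and was not tested.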
